A study of Caenorhabditis elegans with 10 samples.

How the data were processed

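RNA was sequenced from whole N2 larvae, the wild-type C. elegans strain, in 10 libraries. Per the labels' protocols, embryos from bleached adults were kept without food for 24 h at 20 °C, which gave about 12 h of L1 arrest, and the larvae were then fed HB101 bacteria at 25 mg/mL. Samples were taken before feeding and after 1 h, 3 h and 6 h. Per the labels' protocols, RNA was extracted with TRIzol, 200 ng of polyadenylated RNA was decapped with tobacco acid pyrophosphatase and fragmented with RNase III, and inserts of 100 to 200 nt were amplified for 12 PCR cycles and sequenced on a SOLiD 4 instrument. Groups were taken from the titles of the samples. Replicate numbers follow the order of the samples and name no culture shared across groups. They coincide with the barcode sets that were fitted as a block, so libraries of the same number share a set. The series' design text speaks of biological replicates but no separate cultures are named, so p values here measure the spread between these samples, which may be technical.

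The authors aligned the reads with Bowtie 0.12.7 and TopHat, per the submitters' processing notes, and included reads from which the 22 bp spliced leader SL1 or SL2 had been stripped, per the labels. The deposited counts are whole-number read counts per exonic bin and library, made with the DEXSeq scripts for preparing an annotation and counting reads, per the deposited notes. Whether that counting used the strand is not given in the sources used here, so bins that overlap a gene on the other strand are uncertain, as are near-identical paralogs. Of the plus strand, 1164 bins overlap a bin of the minus strand, and overlaps with genes outside the bins were not counted. The gene models were WS210 with noncoding RNAs of WS220, per the annotation's source column. The deposited FPKM values were estimated by the authors with cuffdiff of Cufflinks 1.0.2, with a stranded library type, a mean fragment length of 150 and an SD of 40, per the deposited notes. They hold a single value per gene or transcript and time point, with the libraries pooled, so they carry no SD. The reference annotation used here is of another build, WBcel235, and served for gene symbols only, matched by sequence name. Of 13117 single genes, 12916 matched. Coordinates are those of the deposited WS210 bins.

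The 108516 bins belong to 13374 gene units, and the count of a unit is the sum over its bins, so a read that spans several bins is counted in each. The authors' FPKM table holds 44968 genes, so shares of called units and list members here cover the binned subset alone. Per library, 13143 to 13298 units had a count. Of the 13374 units, 257 merge overlapping genes, and these were tested but not named. Lines for reads outside the bins or ambiguous reads were left out of library sizes. They made up 8.35% to 11.4% of the total for reads outside the bins, and 33 to 98 reads per library were ambiguous. Summed counts ranged from 19163997 to 38607167 per library, and the 10 highest genes took 6.80% to 10.4%. No replicate pair agreed within sampling noise, since chi-square per degree of freedom over genes was 22.1 or more. Floors for a count of 0 use 3 counts over the group and cover counting error only, because PCR copies are not independent molecules.

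Genes were tested in R 4.3.3 with edgeR 4.0.16, with TMM factors (0.813 to 1.20), edgeR's filterByExpr by group and a robust quasi-likelihood fit over all 10 libraries with 4 groups and 6 residual degrees of freedom. The filter kept 13226 units and removed 148. The common biological coefficient of variation was 0.206. The contrasts were 1 h, 3 h and 6 h against starved, 3 h against 1 h, 6 h against 3 h, and a joint test over all times, each with Benjamini-Hochberg adjustment and an adjusted p under 0.05 as the threshold. CPM used library sizes scaled by TMM, and log2 CPM a prior count of 2. Relative bin use was tested with edgeR's diffSpliceDGE and Simes' method per gene on genes with 2 or more kept bins, merged units left out, in 11669 genes and 81201 bins. Bin shares are a bin's counts over those of its gene. Gene lists with 3 or more tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over 34 lists and 3 times (102 tests, of which 65 were called, 23 at 1 h and 21 each at 3 h and 6 h). With a correlation estimated from the data, 0 of the 102 were called, and the smallest adjusted p was 0.0973. The directional test of fry called 79, of which 63 were also called by camera.

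The lists were cytosolic and mitochondrial ribosomal proteins, translation factors, aminoacyl-tRNA synthetases, nucleolar and ribosome biogenesis factors, spliceosome and splicing factors, SR family splicing proteins, nonsense-mediated decay factors, proteasome subunits, oxidative phosphorylation subunits, vacuolar ATPase subunits, enzymes of glycolysis, of glyoxylate metabolism and gluconeogenesis, of fatty acid synthesis, of fatty acid oxidation and of the methionine cycle, DAF-16 and stress-associated genes, heat shock proteins, the insulin pathway, autophagy factors, cuticle collagens, molting genes, cell cycle and DNA replication genes, histones, intestinal proteases, lysozymes and antimicrobial effectors, cytochrome P450 and transferase genes, nuclear hormone receptors, chemoreceptors, neuropeptides and muscle genes. Markers of germline, of oocytes and early embryos, and of adult yolk and sperm stood for other cell types the samples could hold.

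Named genes follow a rule. For each contrast with starved larvae it takes the 8 highest and 8 lowest log2 fold changes among genes with a symbol that are not merged units, have an adjusted p under 0.05 and a mean log2 CPM of 4 or more, and whose groups do not overlap. For the steps between fed times it takes 3 and 3. Each list adds up to 4 members per contrast with the smallest p under the threshold, and bin use adds, per contrast, the 8 genes with a symbol and the smallest p under the threshold, and every tested SR family gene. Genes outside the rule are named where they go against their list or are the few members of a small count, and those were chosen after their values were seen. The lists, tests, rule and alternatives were set before the data were examined, apart from alternatives stated otherwise.

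The tests were tested on simulated counts with known changes. For edgeR on 13068 genes, 2-fold changes were recovered in 38.8% of changed genes at 1 h, 50.7% at 3 h and 59.7% at 6 h, and 4-fold changes in 87.9%, 87.9% and 90.9%. False calls were 5 of 94, 9 of 105 and 5 of 111. These gene simulations changed far fewer genes than were called in the data, in equal numbers up and down. Recovery at an adjusted threshold depends on that number, so it may differ in the data. For bin use on 11342 genes, 4-fold changes were recovered in 40%, 44% and 61% and 8-fold changes in 90%, 86% and 96%. These changes were placed only in bins with many counts, in genes with several kept bins. Recovery for bins with few counts or genes with few bins was not simulated. Median estimates of relative use were 0.755 to 0.801 of the log2 change put in. Alternatives were DESeq2 1.42.0, limma voom, other scalings (DESeq2 size factors, upper quartile, library totals alone), filters of 20 or more counts in 2 libraries or a total of 1, a fold threshold of 1.5, the highest-count bin per gene, fits to the groups compared alone, barcode number over 8 as a covariate, barcodes 1 to 4, 5 to 8 and over 8 as a block, barcodes 1 to 8 alone and each library left out. The log2 ratio of FPKM used a pseudocount of 1, with 0.1 and 5 or a minimum of 1 FPKM as alternatives. For shared controls, 20 simulated sets of unchanged groups gave the overlap, without any change, of as many genes with the smallest p in each direction as were called in the data.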

Results

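Polyadenylated RNA was sequenced from whole wild-type (N2) Caenorhabditis elegans larvae of the first stage, L1, as they recovered from arrest. Larvae that hatch without food stop developing in L1 and resume growth when they are fed. The 10 libraries formed 4 groups. Starved larvae, taken about 12 h into arrest, gave 3 libraries, and larvae collected 1 h, 3 h and 6 h after feeding with the E. coli strain HB101 gave 2, 2 and 3 libraries. The comparisons ask which transcripts change after feeding, how early they do so, and whether the parts of a gene that are covered by reads change as well. Counts summed over exonic bins, the separate pieces into which the exons of a gene were divided, ranged from 19163997 in replicate 1 at 3 h to 38607167 in replicate 2 of the starved larvae. Levels below are CPM, counts scaled by the effective size of each library, given as mean ± SD over the libraries of a group, and fold changes are log2 values ± SE. Adjusted p values of genes come from edgeR's quasi-likelihood test and those of gene lists from limma's camera. No unfed library from 1 h, 3 h or 6 h was analysed here, so each comparison with starved larvae covers feeding and elapsed time together.

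The libraries separated first by feeding and then by time. The first principal component of log2 CPM held 56.9% of the variance and the second 17.6%. Pearson correlations of log2 CPM across genes, which are not independent replicates, lay between 0.979 and 0.993 within groups and between 0.885 and 0.914 for starved against fed libraries. Reads outside the bins made up 10.4 ± 0.913% in starved larvae, 9.78 ± 0.0741% at 1 h, 8.80 ± 0.271% at 3 h and 8.54 ± 0.209% at 6 h.

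**Figure D1:**
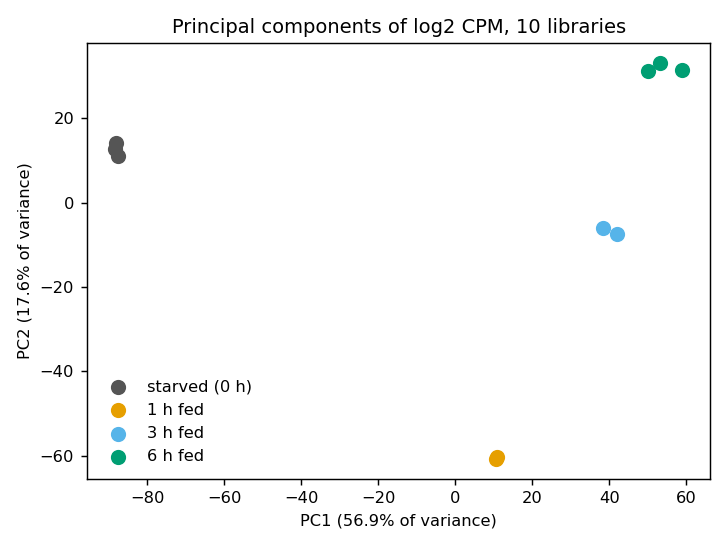
Principal components of log2 CPM over the tested genes, with the first component (56.9% of the variance) on the x axis, the second (17.6%) on the y axis and a point for each of the 10 libraries, coloured by group. Starved and fed libraries lie apart along the first component.

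At 1 h after feeding, several metabolic enzyme genes were far below the starved level. The acyl-CoA synthetase gene acs-2, which acts in mitochondrial fatty acid oxidation, fell from 2878 ± 352 to 42.8 ± 5.15 CPM. The gene icl-1, which encodes the glyoxylate cycle enzyme that lets worms make sugar from fat, fell from 4663 ± 442 to 197 ± 30.5 CPM. The alcohol dehydrogenase gene adh-1 fell from 8314 ± 1430 to 105 ± 18.6 CPM, and the linker histone gene hil-1 from 259.6 ± 5.83 to 4.53 ± 0.272 CPM. The fall of acs-2 went against its list at 1 h, since fatty acid oxidation and lipolysis genes had 24 of 50 members higher and 6 lower (24 and 6 adjusted over the list alone, adjusted p = 0.00943, and adjusted p = 0.313 with an estimated correlation). The peroxisomal acyl-CoA oxidase gene acox-1.1 of that list rose from 29.6 ± 2.74 to 285 ± 8.98 CPM. The list was not called later. At 3 h 14 rose and 16 fell (14 and 16 adjusted over the list alone, adjusted p = 0.598, and adjusted p = 0.811 with an estimated correlation). At 6 h 22 rose and 12 fell (23 and 12 adjusted over the list alone, adjusted p = 0.205, and adjusted p = 0.604 with an estimated correlation). Also at 1 h, the UDP-glucuronosyltransferase gene ugt-63 rose from 0.739 ± 0.173 to 177 ± 2.27 CPM and the arginine kinase gene argk-1 from 2.22 ± 1.04 to 100.1 ± 5.11 CPM.

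Apart from acox-1.1, these genes were among the 8 with the largest rise and the 8 with the largest fall of the genes that have a symbol and a mean log2 CPM of 4 or more and whose groups do not overlap. Genes of lower level are left out of this ranking and of those below, and some of them changed by more. adh-1 (K12G11.3, chromosome V, 11888214 to 11889628 in the WS210 genome build) changed by a log2 value of -6.30 ± 0.31 with an adjusted p of 5.71e-09. acs-2 (F28F8.2, chromosome V, 15567367 to 15569864) changed by -6.07 ± 0.36, and ugt-63 (C04F5.7, chromosome V, 5108000 to 5110774) by 7.86 ± 0.21 with an adjusted p of 2.31e-11. The ferritin gene ftn-1 fell from 68.6 to 2.24 CPM, aakg-4, which encodes a subunit of AMP-activated protein kinase, from 149.3 to 9.25 CPM, the nuclear receptor gene nhr-19 from 146 to 9.89 CPM, and dap-1 from 1126 to 100.8 CPM. Rises were measured for the cysteine synthase family gene cysl-2, from 17.4 to 610.4 CPM, the lipase family gene lips-10, from 3.05 to 113 CPM, the cytochrome P450 gene cyp-35C1, from 1.80 to 48.8 CPM, the peptidase gene pcp-2, from 2.39 to 59.9 CPM, ugt-22, from 3.38 to 81.0 CPM, and dct-17, from 1.06 to 46.5 CPM.

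Genes for making ribosomes and proteins rose together at 1 h. Of the 32 nucleolar and ribosome biogenesis genes, 25 rose and 1 fell (27 and 1 adjusted over the list alone, adjusted p = 3.33e-11, and adjusted p = 0.269 with an estimated correlation). The snoRNP genes nol-56 and nol-58 rose from 165 ± 15.6 to 968 ± 49.5 CPM and from 109 ± 23.8 to 840.4 ± 27.1 CPM. The member that fell, imp-3, is an intramembrane protease gene. Of the 39 translation factor genes, 28 rose and 0 fell (28 and 0 adjusted over the list alone, adjusted p = 2.89e-09, and adjusted p = 0.269 with an estimated correlation), among them inf-1, the eIF4A gene, from 150.2 ± 22.0 to 857 ± 45.3 CPM, and eif-3.C, from 77.7 ± 11.1 to 511 ± 32.7 CPM. Of the 30 aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, 22 rose and 0 fell (23 and 0 adjusted over the list alone, adjusted p = 9.01e-08, and adjusted p = 0.292 with an estimated correlation), among them nars-1, from 49.6 ± 4.37 to 245 ± 15.1 CPM, and fars-1, from 34.5 ± 2.25 to 158 ± 8.0 CPM. Among 60 spliceosome and splicing factor genes, 36 rose and 2 fell (36 and 2 adjusted over the list alone, adjusted p = 7.13e-07, and adjusted p = 0.238 with an estimated correlation), and eftu-2, a core spliceosome GTPase gene, rose from 88.7 ± 12.9 to 237 ± 23.4 CPM. The splicing factor genes that fell were uaf-1, which recognises the 3' splice site, and rbm-25.

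Genes for protein folding and for the methionine cycle rose as well. Of 49 heat shock protein and co-chaperone genes, 33 rose and 3 fell (33 and 3 adjusted over the list alone, adjusted p = 1.53e-07, and adjusted p = 0.136 with an estimated correlation), with dnj-11 going from 28.9 ± 5.78 to 315 ± 5.14 CPM and hsp-110 from 89.6 ± 13.8 to 561 ± 68.1 CPM. Of 13 genes of the methionine and S-adenosylmethionine cycle, 8 rose and 1, dao-3, fell (8 and 1 adjusted over the list alone, adjusted p = 5.50e-04, and adjusted p = 0.136 with an estimated correlation). The cystathionine gamma-lyase gene cth-1 rose from 31.2 ± 1.66 to 349 ± 13.5 CPM and the cystathionine beta-synthase gene cbs-1 from 17.1 ± 3.03 to 171 ± 6.34 CPM. Fatty acid synthesis and desaturation genes had 10 of 19 members higher and 2 lower (10 and 2 adjusted over the list alone, adjusted p = 0.0193, and adjusted p = 0.216 with an estimated correlation), and the elongase gene elo-2 rose from 199.7 ± 29.1 to 1031 ± 43.1 CPM. That list was not called later. At 3 h 7 rose and 6 fell (7 and 6 adjusted over the list alone, adjusted p = 0.557, and adjusted p = 0.691 with an estimated correlation). At 6 h 8 rose and 6 fell (8 and 6 adjusted over the list alone, adjusted p = 0.705, and adjusted p = 0.793 with an estimated correlation). The sign of its median at these times depended on scaling (-0.14 to 0.12 and -0.24 to 0.09 over 4 scalings). Intestinal protease and lysosomal hydrolase genes had 16 of 36 members higher and 5 lower (17 and 5 adjusted over the list alone, adjusted p = 0.0390, and adjusted p = 0.269 with an estimated correlation), and the oligopeptide transporter gene pept-1 rose from 64.7 ± 8.83 to 384 ± 19.1 CPM. The call of the list intestinal proteases and lysosomal hydrolases at 1 h was lost without starved replicate 1 (adjusted p = 0.0523) and without replicate 2 at 6 h (adjusted p = 0.0606).

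Autophagy, stress and neuropeptide genes fell at 1 h. Of 25 autophagy genes, 16 fell and 0 rose (18 and 0 adjusted over the list alone, adjusted p = 1.01e-05, and adjusted p = 0.0973 with an estimated correlation). The ubiquitin-like autophagosome gene lgg-1 fell from 635 ± 119 to 135 ± 9.52 CPM and atg-18 from 338 ± 63 to 69.1 ± 3.30 CPM. The list of DAF-16 and stress-associated genes joins genes tied to the stress transcription factor DAF-16 with other stress genes. Of its 23 members, 15 fell and 1 rose (15 and 2 adjusted over the list alone, adjusted p = 1.28e-04, and adjusted p = 0.122 with an estimated correlation), and the metallothionein gene mtl-1 fell from 52.5 ± 15.8 to 1.26 ± 0.496 CPM. Glyoxylate and gluconeogenesis genes had 6 of 12 members lower and 1 higher (8 and 1 adjusted over the list alone, adjusted p = 0.00408, and adjusted p = 0.349 with an estimated correlation), with the trehalose synthase gene tps-1 going from 299 ± 36.9 to 68.1 ± 1.78 CPM. At 6 h that list was not called, and 2 rose and 5 fell (2 and 5 adjusted over the list alone, adjusted p = 0.101, and adjusted p = 0.596 with an estimated correlation). Of 56 neuropeptide genes, 28 fell and 2 rose (33 and 2 adjusted over the list alone, adjusted p = 1.58e-05, and adjusted p = 0.270 with an estimated correlation), and flp-9 fell from 461 ± 86.9 to 206 ± 33.1 CPM. Of 99 cuticle collagen genes, 34 fell and 1 rose (30 and 0 adjusted over the list alone, adjusted p = 2.32e-05, and adjusted p = 0.485 with an estimated correlation).

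Cytosolic ribosomal protein genes were not higher at 1 h. Of the 69 members, 0 rose and 5 fell (0 and 0 adjusted over the list alone), and the median log2 fold change was -0.30. Camera called the list lower with an adjusted p of 0.00457, and adjusted p = 0.691 with an estimated correlation. That call was lost without starved replicate 3 (adjusted p = 0.0942), without replicate 2 at 1 h (adjusted p = 0.209) and with the libraries of barcodes 1 to 8 (adjusted p = 0.0762). The genes that fell were rpl-23A.1, rpl-28, rpl-37A, rpl-38 and rpl-35, and each of the first 4 lost its call when at least 1 library was left out, which was not examined for rpl-35.

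In all, 2696 of 13226 tested gene units were higher and 2467 lower at 1 h, which is 39% of them. Of the called units, 1505 were more than 2-fold higher and 1495 more than 2-fold lower. The count fell to 3331 without replicate 1 at 1 h and to 3307 without replicate 2, and in each case the remaining library was assumed to vary like the other groups. The 8 libraries with barcodes 1 to 8 gave 4965 genes at 1 h, 5488 at 3 h and 6364 at 6 h.

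**Figure D2:**
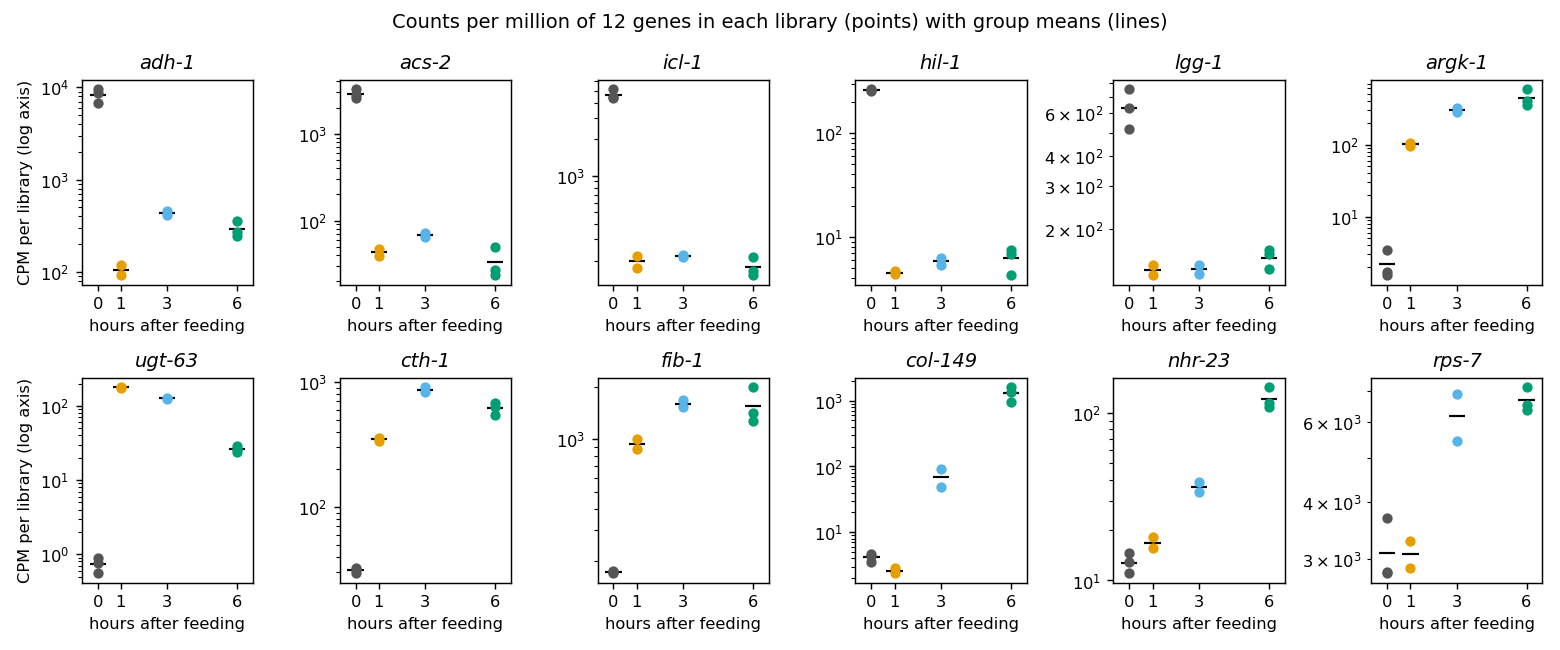
CPM on a log axis against hours after feeding (0 h is starved) for 12 genes, with a point per library and a short line at each group mean. acs-2, icl-1, adh-1, hil-1 and lgg-1 lie lower at 1 h, 3 h and 6 h than in starved larvae, and col-149 and nhr-23 have their highest means at 6 h.

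At 3 h the ribosomal protein genes had risen. Of 69 cytosolic ribosomal protein genes, 49 rose and 0 fell (56 and 0 adjusted over the list alone, adjusted p = 3.91e-09, and adjusted p = 0.387 with an estimated correlation), and rps-7 went from 3095 ± 514 to 6177 ± 1046 CPM. Mitochondrial ribosomal protein genes had 51 of 59 members higher and 3 lower (52 and 3 adjusted over the list alone, adjusted p = 4.10e-13, and adjusted p = 0.141 with an estimated correlation), after 42 higher and 3 lower at 1 h. Proteasome subunit genes had 27 of 29 members higher and 1 lower (27 and 1 adjusted over the list alone, adjusted p = 5.66e-09, and adjusted p = 0.122 with an estimated correlation), with the core particle gene pas-7 going from 43.8 ± 1.88 to 117 ± 3.41 CPM. acs-2 and icl-1 stayed low, with acs-2 at 67.6 ± 4.75 CPM and icl-1 at 217 ± 7.01 CPM.

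The members that went against these lists were few and can be named. mrps-11, mrpl-41 and mrpl-55 fell among the mitochondrial ribosomal protein genes, mrps-11 from 148 ± 35.1 to 49.7 ± 4.41 CPM. rpn-6.2 fell among the proteasome genes, from 6.85 ± 2.77 to 2.52 ± 1.17 CPM. All 4 were chosen after their values were seen.

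argk-1 (F44G3.2, chromosome V, 16103868 to 16106114) rose by a log2 value of 7.05 ± 0.33, to 303 ± 25 CPM, with an adjusted p of 3.32e-09. The saposin-like gene spp-17 rose from 1.93 to 89.8 CPM, the astacin protease gene nas-3 from 1.29 to 52.9 CPM, and the proton-coupled myo-inositol transporter gene hmit-1.1 from 2.28 to 80.7 CPM, while ugt-63, ugt-22, dct-17 and pcp-2 were again among the 8 largest rises of genes with a mean log2 CPM of 4 or more. The fatty acid and retinol binding protein gene far-7 (K01A2.2, chromosome II, 319792 to 321106) fell from 171 ± 31.4 to 6.52 ± 0.899 CPM, the glutamate-gated chloride channel gene glc-1 from 83.9 ± 13 to 5.32 ± 1.89 CPM, and the paralogs poml-3 and poml-4 from 274 to 13.9 CPM and from 233 to 11.2 CPM.

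Ribosome biogenesis, translation and methionine cycle genes were higher at 3 h as well, and autophagy genes and the DAF-16 and stress-associated genes lower. Biogenesis genes had 26 of 32 members higher and 1 lower (27 and 1 adjusted over the list alone, adjusted p = 1.93e-11, and adjusted p = 0.269 with an estimated correlation), and the fibrillarin gene fib-1 rose from 173 ± 2.54 to 1596 ± 102 CPM. Translation factor genes had 32 of 39 members higher and 0 lower (32 and 0 adjusted over the list alone, adjusted p = 7.08e-12, and adjusted p = 0.234 with an estimated correlation). For methionine cycle genes the numbers were 10 of 13 higher and 0 lower (10 and 0 adjusted over the list alone, adjusted p = 1.90e-05, and adjusted p = 0.0973 with an estimated correlation), and ahcy-1, which removes the inhibitory product of methylation reactions, rose from 975 ± 193 to 6408 ± 712 CPM. Autophagy genes had 14 of 25 members lower and 1 higher (14 and 1 adjusted over the list alone, adjusted p = 2.37e-04, and adjusted p = 0.0973 with an estimated correlation). DAF-16 and stress-associated genes had 13 of 23 lower and 3 higher (15 and 3 adjusted over the list alone, adjusted p = 7.57e-04, and adjusted p = 0.136 with an estimated correlation).

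Glycolysis genes were lower at 3 h. Of 15 members 6 fell and 0 rose (6 and 0 adjusted over the list alone, adjusted p = 0.0312, and adjusted p = 0.386 with an estimated correlation), and the aldolase gene aldo-2 fell from 3935 ± 142 to 925 ± 43.7 CPM. The list was not called at 1 h or 6 h. At 1 h 0 rose and 4 fell (0 and 4 adjusted over the list alone, adjusted p = 0.105, and adjusted p = 0.493 with an estimated correlation). At 6 h 4 rose and 7 fell (4 and 7 adjusted over the list alone, adjusted p = 0.289, and adjusted p = 0.667 with an estimated correlation). The list call was lost without replicate 1 at 3 h (adjusted p = 0.0693) and with the libraries of barcodes 1 to 8 (adjusted p = 0.0609).

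At 3 h, 2896 gene units were higher and 2605 lower, 41.6% of the 13226 tested. The split depended on scaling. Scaling by library totals alone, without the TMM factors, gave 3073 higher and 1977 lower at 1 h, 2014 and 3570 at 3 h, and 2345 and 4959 at 6 h. Upper-quartile scaling gave 2247 higher and 3037 lower at 1 h, 2400 and 3211 at 3 h, and 2814 and 4368 at 6 h. Totals alone also moved the median log2 fold change of all genes, to 0.11 at 1 h, -0.26 at 3 h, -0.37 at 6 h and -0.37 from 1 h to 3 h, against -0.04 to 0.01 with TMM, and upper-quartile factors moved it to -0.13, -0.16 and -0.24 at the 3 times. Levels here are therefore relative to the bulk of the genes in a library. No list that camera called changed the sign of its median with any of the 4 scalings at 1 h, 3 h or 6 h.

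By 6 h, molting genes stood above the starved level, whereas cuticle collagen genes went both ways. The cuticle collagen gene col-149 rose from 4.17 ± 0.581 to 1312 ± 322 CPM. The nuclear receptor gene nhr-23, a regulator of the molt, rose from 12.8 ± 1.74 to 122 ± 18.2 CPM, and noah-1, which encodes a protein of the apical extracellular matrix, from 5.32 ± 1.64 to 206 ± 58.1 CPM. Of 37 molting and cuticle remodelling genes, 22 rose and 2 fell (23 and 2 adjusted over the list alone, adjusted p = 2.25e-06, and adjusted p = 0.234 with an estimated correlation), after 17 higher and 3 lower at 3 h (17 and 4 adjusted over the list alone, adjusted p = 0.00943, and adjusted p = 0.411 with an estimated correlation). Cuticle collagens were not called at 3 h, when 17 rose and 19 fell (17 and 18 adjusted over the list alone, adjusted p = 0.796, and adjusted p = 0.981 with an estimated correlation). At 6 h they had 20 of 99 members higher and 31 lower, and the list was not called (21 and 31 adjusted over the list alone, adjusted p = 0.129, and adjusted p = 0.793 with an estimated correlation). col-107 fell from 273 ± 38.1 to 21.1 ± 5.64 CPM.

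**Figure D3:**
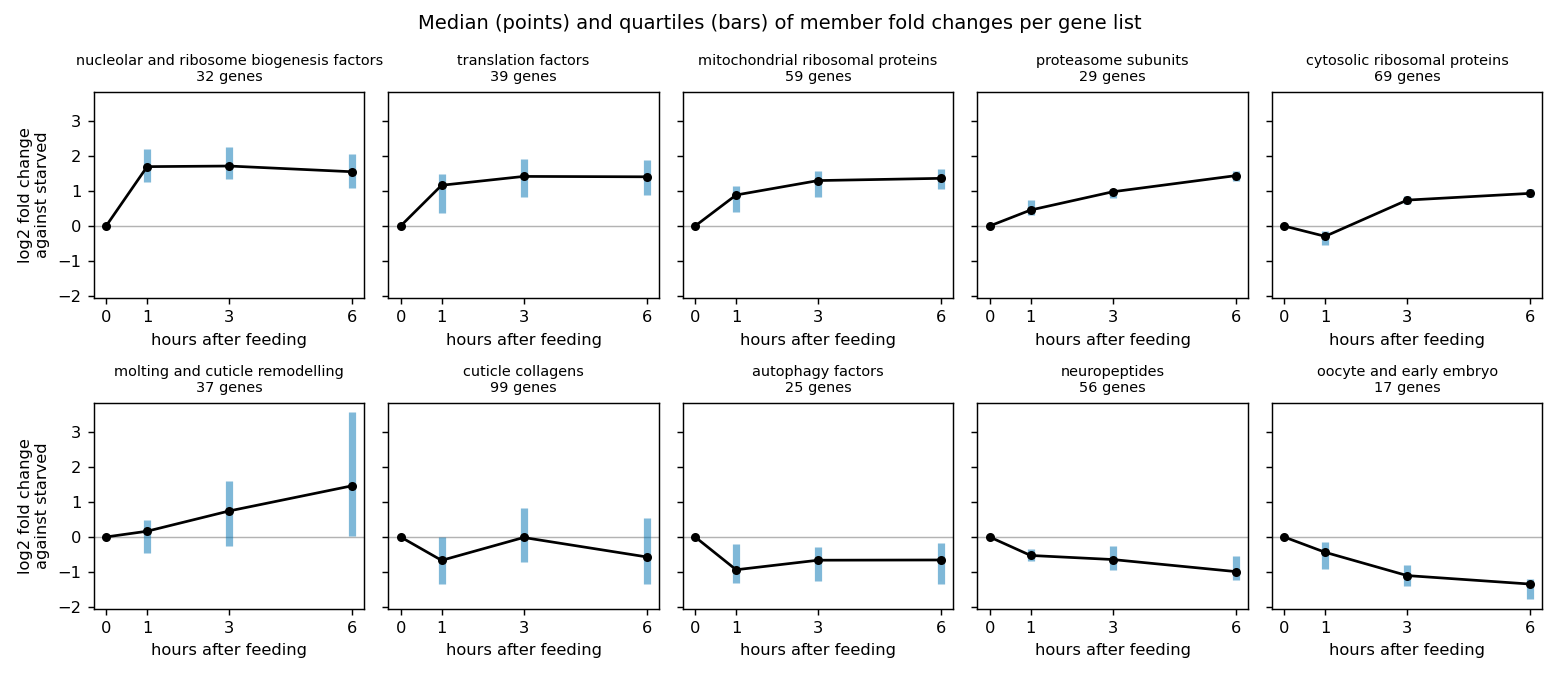
Median (points) and quartiles (bars) of the log2 fold changes of list members against starved larvae, plotted against hours after feeding for 10 gene lists. Cytosolic ribosomal protein genes go from a median of -0.30 at 1 h to 0.94 at 6 h, while nucleolar and ribosome biogenesis genes are at 1.70 by 1 h.

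Growth and division genes were higher at 6 h. Cell cycle and DNA replication genes had 39 of 55 members higher and 2 lower (39 and 2 adjusted over the list alone, adjusted p = 5.95e-07, and adjusted p = 0.166 with an estimated correlation), and the replicative helicase gene mcm-4 rose from 32.7 ± 4.96 to 93.2 ± 19.2 CPM. At 1 h 27 rose and 1 fell (29 and 2 adjusted over the list alone, adjusted p = 1.12e-04, and adjusted p = 0.234 with an estimated correlation). At 3 h 24 rose and 2 fell (26 and 2 adjusted over the list alone, adjusted p = 4.32e-04, and adjusted p = 0.266 with an estimated correlation). The 2 that fell at 6 h were the cyclin B paralogs cyb-2.1 and cyb-2.2. All 28 other proteasome genes rose and rpn-6.2 fell (28 and 1 adjusted over the list alone, adjusted p = 7.08e-12, and adjusted p = 0.0973 with an estimated correlation). Cytosolic ribosomal protein genes had 66 of 69 members higher and 0 lower (67 and 0 adjusted over the list alone, adjusted p = 1.93e-11, and adjusted p = 0.348 with an estimated correlation), with rpl-11.2 going from 1447 ± 190.2 to 3553 ± 682 CPM. Vacuolar ATPase genes, whose products acidify organelles, had 11 of 19 members higher and 0 lower (11 and 0 adjusted over the list alone, adjusted p = 0.00738, and adjusted p = 0.295 with an estimated correlation). Oxidative phosphorylation genes had 18 of 44 higher and 3 lower (17 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.0539, and adjusted p = 0.354 with an estimated correlation).

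Markers of oocytes and early embryos were higher in starved larvae than at 6 h. Of 17 such genes, 13 fell and 1 rose (13 and 1 adjusted over the list alone, adjusted p = 9.90e-04, and adjusted p = 0.354 with an estimated correlation). The eggshell gene cpg-1 fell from 29.2 ± 6.40 to 3.87 ± 1.81 CPM, the egg activation pseudophosphatase gene egg-5 from 8.83 ± 0.264 to 2.0 ± 0.415 CPM and oma-2, which acts in oocyte maturation, from 8.22 ± 2.99 to 2.61 ± 0.218 CPM. The gene that rose was mex-3, from 40.8 ± 14.3 to 72 ± 9.16 CPM. At 3 h, 7 had fallen and 0 had risen (8 and 0 adjusted over the list alone, adjusted p = 0.00642, and adjusted p = 0.431 with an estimated correlation). Germline genes had 6 of 31 members higher and 10 lower at 6 h (6 and 10 adjusted over the list alone) and the list was not called (adjusted p = 0.118, and adjusted p = 0.737 with an estimated correlation), and the Argonaute gene prg-1 rose from 22.2 ± 2.26 to 49.7 ± 6.55 CPM. Markers of adult yolk and sperm had 1 of 7 lower at 6 h, msp-31, and 0 higher (0 and 0 adjusted over the list alone, adjusted p = 0.502, and adjusted p = 0.790 with an estimated correlation). The call of msp-31 at 6 h was lost without starved replicate 2 (adjusted p = 0.0760), replicate 1 at 6 h (adjusted p = 0.0681) or replicate 2 at 6 h (adjusted p = 0.0743).

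Among genes with a symbol and a mean log2 CPM of 4 or more, the largest falls at 6 h were those of acs-2 (-6.44 ± 0.31, adjusted p = 1.48e-09) and hil-1 (-5.39 ± 0.21). ram-2 fell from 503 ± 153 to 16.9 ± 5.48 CPM, and adh-1, icl-1, poml-3, poml-4 and far-7 made up the rest of the 8. Above the same cut, the largest rises besides col-149 (B0024.1, chromosome V, 10291667 to 10292839, log2 change 8.29 ± 0.33) were argk-1, to 447 ± 121 CPM, nas-3, to 184 ± 12.5 CPM, the leucine-rich repeat gene sym-1, to 611 ± 200.3 CPM, ugt-22, spp-17, dct-17 and the invertebrate lysozyme gene ilys-5, to 135 ± 22.1 CPM. At 6 h, 3570 gene units were higher and 3303 lower, 52.0% of those tested.

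The step from 1 h to 3 h changed 633 units upward and 608 downward. The collagen gene col-149 rose from 2.61 ± 0.332 to 70 ± 29.7 CPM, nas-3 from 6.10 ± 0.419 to 52.9 ± 7.73 CPM and the glutathione S-transferase gene gst-24 from 28.3 ± 0.486 to 215 ± 4.03 CPM. cysl-2 fell back from 610.4 ± 43.8 to 26.2 ± 6.10 CPM (log2 -4.54 ± 0.43, adjusted p = 3.64e-05), and poml-4 and poml-3 fell from 119.5 to 11.2 CPM and from 138 to 13.9 CPM. Library totals alone gave 246 higher and 1707 lower for this step. Its count was 377 without replicate 1 at 1 h, 349 without replicate 2 at 1 h, 502 without replicate 1 at 3 h and 302 without replicate 2 at 3 h.

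The step from 3 h to 6 h changed 278 units upward and 88 downward. The 3 largest rises of genes with a symbol and a mean log2 CPM of 4 or more were those of sym-1, which went from 32.6 ± 9.69 to 611 ± 200.3 CPM, col-149 from 70 ± 29.7 to 1312 ± 322 CPM and noah-1 from 13.9 ± 3.77 to 206 ± 58.1 CPM. ram-2 fell from 96.2 ± 24.9 to 16.9 ± 5.48 CPM, ugt-63 from 127 ± 3.15 to 26.2 ± 2.53 CPM and col-107 from 76.5 ± 8.41 to 21.1 ± 5.64 CPM. Library totals alone gave 198 higher and 116 lower. The count was 120 without replicate 1 at 3 h and 125 without replicate 2.

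Most genes called early were called in the same direction later. Of the 2696 units higher at 1 h, 2097 (77.8%) were also higher at 6 h, where independent lists of these sizes would share 728, and of the 2467 lower at 1 h, 1815 (73.6%) were also lower, against 616. From 3 h to 6 h the shared numbers were 2634 of 2896 (91.0%) and 2234 of 2605 (85.8%), against 782 and 651. Both comparisons use the same starved libraries. Almost nothing was called in 20 simulations of groups without any change. The same numbers of genes with the smallest p in each direction were therefore compared there, and shared 1391 and 1159 units on average for 1 h and 6 h and 1463 and 1217 for 3 h and 6 h. The covariance of the log2 fold changes at 1 h and 6 h across genes was 1.05, against 0.0507 in the simulations, with a correlation of 0.714 against 0.434. The difference in covariance, 1.00, is not given by the shared controls, which add the same covariance with or without a change. Part of the excess of the shared numbers over independent lists may come from the shared controls. Over all times together, 7379 units (55.8%) changed.

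Some genes changed in which of their exonic bins carried the reads. prps-1, a phosphoribosyl pyrophosphate synthetase gene of nucleotide synthesis, gained reads in bin 6 (chromosome III, 7212461 to 7212577), which belongs to a single annotated transcript. That bin held 0.270 ± 0.138% of the gene's counts in starved larvae and 3.63 ± 0.0381% at 1 h, 4.37 ± 0.893% at 3 h and 3.66 ± 2.46% at 6 h (SD, n = 3, 2, 2 and 3). In rpl-31, a ribosomal protein gene, bin 8 (chromosome I, 13653363 to 13653481) went from 0.575 ± 0.298% of the gene's counts to 4.59 ± 0.152% at 3 h. In tos-1, which was lower as a gene at 1 h, bin 7 (chromosome V, 9343770 to 9343918) went from 5.58 ± 1.97% to 19 ± 1.19%.

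At 6 h the cadherin gene cdh-10 gained coverage on both sides of the 3 bins that held most of its reads in starved larvae. Bin 11 of that gene (chromosome IV, 2455104 to 2455652) held 0 of 2047 counts in starved larvae, which allows a share of up to 0.147%, and 10.1 ± 1.35% at 6 h (adjusted p = 6.44e-09 for the gene). Bins 10 to 21 (chromosome IV, 2454356 to 2463367, the 5' part of the gene) together held 1 count in the starved libraries, 2 at 1 h, 6 at 3 h and 785 at 6 h, or 48.2 ± 4.45% of the gene. Bins 7 to 9 (chromosome IV, 2441571 to 2444343) held 97.2 ± 0.610% of the gene's counts in starved larvae and 23.3 ± 3.56% at 6 h. Their level had already fallen by 1 h, from 20.8 ± 5.48 to 6.47 ± 0.835 CPM. It was 6.00 ± 0.998 CPM at 3 h and 5.98 ± 1.24 CPM at 6 h. Bins 1 to 6 (chromosome IV, 2436513 to 2441243, the 3' part) held 57 counts in starved larvae and 449 at 6 h, or 2.68 ± 0.740% and 28.5 ± 1.99% of the gene. The gene as a whole was not called at 6 h, with a log2 change of 0.29 and an adjusted p of 0.317. In the cyclin D gene cyd-1, which drives entry into the cell cycle, bins 1 and 2 (chromosome II, 12980500 to 12982117), annotated to the longer of its transcripts alone, held 1 count in starved larvae, 0 at 1 h, 5 at 3 h and 156 at 6 h, or 4.01 ± 0.297% of the gene. Bin 8 (chromosome II, 12992751 to 12993028), annotated to the longer transcript alone as well, held 15 ± 2.35% of the gene's counts in starved larvae and 11.5 ± 2.40% at 6 h. These bin ranges of cdh-10 and cyd-1 were chosen after the values of their bins were seen.

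**Figure D4:**
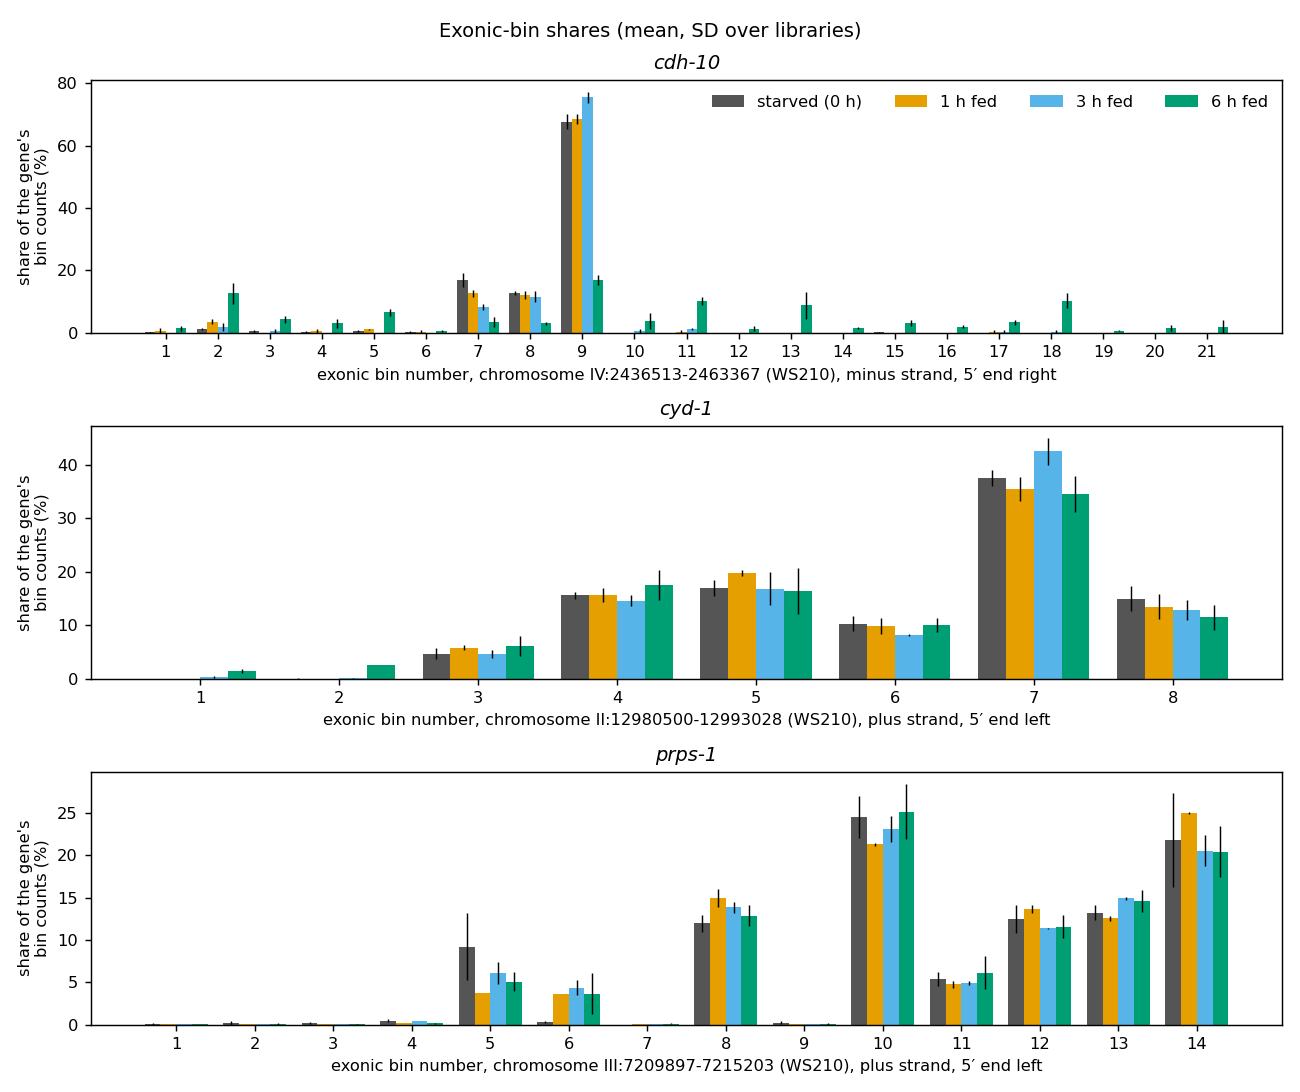
Share of each gene's counts held by each exonic bin, in percent, for cdh-10, cyd-1 and prps-1, with bars from 0 for the group means of starved larvae and of larvae at 1 h, 3 h and 6 h, and error bars for the SD over libraries. Bins 10 to 21 of cdh-10 and bins 1 and 2 of cyd-1 are near 0 in starved larvae and hold reads at 6 h, bins 1 to 6 of cdh-10 hold a larger share at 6 h than in starved larvae, and bin 6 of prps-1 holds more at the 3 fed times.

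Splicing regulators of the SR family rose, and some of them changed in bin use. All 5 tested members rose at each time (5 and 0 adjusted over the list alone), with adjusted p = 8.02e-04 at 1 h, 0.00164 at 3 h and 0.00520 at 6 h, and adjusted p = 0.230, 0.234 and 0.269 with an estimated correlation. rsp-5 rose from 59.7 ± 8.50 to 213 ± 7.30 CPM at 1 h and rsp-1 from 119 ± 10.7 to 305 ± 23 CPM at 6 h. Bin use was called for 3 of the 5 at 1 h, 1 at 3 h and 3 at 6 h. In rsp-3, called at each time (adjusted p = 0.00109, 0.00112 and 3.50e-04), bin 2 (chromosome III, 12686387 to 12686582) held 11.7 ± 5.06% of counts in starved larvae and 2.69 ± 0.195% at 1 h, 2.63 ± 0.215% at 3 h and 3.33 ± 0.383% at 6 h. In rsp-6, bin 8 (chromosome IV, 7790487 to 7790728) went from 15 ± 4.19% to 4.58 ± 0.392% at 1 h (adjusted p = 0.0386) and 5.50 ± 0.985% at 6 h (adjusted p = 0.0328). The gene was not called at 3 h (adjusted p = 0.309), although the bin held 5.30 ± 0.458% there. In rsp-1, bin 6 (chromosome II, 11454558 to 11454940), which belongs to a single transcript, went from 8.37 ± 0.842% to 3.17 ± 0.12% at 6 h (adjusted p = 0.00920). The gene was not called at 1 h or 3 h (adjusted p = 0.594 and 0.673), although the bin held 3.76 ± 0.759% and 3.59 ± 0.214% there, near its share at 6 h. In rsp-5, bin 5 (chromosome II, 6490671 to 6490751) went from 6.95 ± 1.68% to 2.1 ± 0.126% at 1 h (adjusted p = 0.0365). At 6 h that bin held 2.97 ± 1.26%. The gene was not called at 3 h or 6 h (adjusted p = 1 and 0.230). rsp-7 was not called at any time. The bin shares above fell while their genes rose. The level of bin 6 of rsp-1 was 9.89 ± 0.204 CPM in starved larvae and 9.66 ± 0.356 CPM at 6 h. From starved larvae to 1 h, bin 5 of rsp-5 went from 4.09 ± 0.823 to 4.47 ± 0.115 CPM. Over the same step bin 8 of rsp-6 went from 16.9 ± 5.01 to 12.8 ± 1.96 CPM and bin 2 of rsp-3 from 10.6 ± 5.37 to 4.13 ± 0.994 CPM.

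Among genes with a symbol, others with the smallest p for bin use were gpcp-2 at each time, col-168 at 1 h and 3 h, kcc-1 and plin-1 at 1 h, dig-1, iff-2 and tat-4 at 3 h, and hel-1, erd-2.1 and sams-1 at 6 h. Genes without a symbol were left out of this choice, and 1 of them had the smallest p of all at 3 h and 6 h. In the S-adenosylmethionine synthetase gene sams-1, bin 9 (chromosome X, 11969578 to 11969707) went from 0.428 ± 0.171% of counts to 0.0386 ± 0.0175%, while the gene rose by a log2 value of 3.03. In the RNA helicase gene hel-1, bin 3 (chromosome II, 8327653 to 8327818) went from 2.99 ± 0.772% to 0.861 ± 0.0997%, while the gene rose by a log2 value of 1.60. edgeR's test of relative bin use called 45 genes at 1 h, 23 at 3 h and 67 at 6 h of 11669 tested, 90 at any time and 15 at all 3, and 28, 19 and 45 of them were also called at the gene level. The count at 1 h was 127 without starved replicate 1, 19 without starved replicate 2, 3 and 5 without replicates 1 and 2 at 1 h, and 24 without either library at 3 h, and the count at 3 h was 15 without either library at 1 h and 5 and 7 without replicates 1 and 2 at 3 h. The calls of prps-1, gpcp-2, rpl-31, cdh-10, cyd-1, hel-1, erd-2.1 and sams-1 were kept without any single library, as was that of rsp-3 at 6 h, whereas those of tos-1, kcc-1, plin-1, dig-1, iff-2, tat-4, rsp-1, rsp-5 and rsp-6, of rsp-3 at 1 h and 3 h and of col-168 at 1 h were lost without at least 1 library.

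The authors' own FPKM values, which pool the libraries of a time point, were set beside these counts. Across 12969 genes, which are not independent replicates, log2 ratios of FPKM + 1 against starved larvae had a Spearman correlation with the fold changes here of 0.965 at 1 h, 0.956 at 3 h and 0.952 at 6 h. Of the genes called here, 99.96% had the same sign in the FPKM table at 1 h, 99.4% at 3 h and 98.0% at 6 h. The authors' transcript estimates come from the same libraries and so are not independent of the bin counts. Where the leading bin of a gene named for bin use belonged to a single one of its transcripts, that transcript's share of the gene's FPKM moved in the direction of the bin's share in 10 of 12 cases. These came from 8 genes, with prps-1 and rpl-31 counted at 3 times each. In prps-1 the transcript of bin 6 stood at 4.23 FPKM in starved larvae and at 166 FPKM at 1 h. The 2 exceptions were 2 of the 8 genes, each counted at 6 h alone. The longer transcript of cyd-1, which holds bins 1 and 2, went from 48.3% of the gene's FPKM in starved larvae to 47.0% at 6 h. The transcript of sams-1 that holds bin 9 went from 33.6 to 603 FPKM, from 10.1% to 26.5% of the gene, while the bin's share fell.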

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

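The tests for adult remains, unhatched embryos, library scaling and a shift of coverage, and the comparisons with genes of like length alone or like level alone, were chosen only after the results they bear on were seen. Changes from starved larvae differed between 1 h and 6 h in edgeR's test of the difference for 3249 genes. Of these, 45 were higher at 1 h and lower at 6 h than in starved larvae, and 59 were lower at 1 h and higher at 6 h. Camera called 18 lists for the difference between 6 h and 1 h, and 0 lists were called with an estimated correlation. The median log2 difference of the cytosolic ribosomal protein genes between 6 h and 1 h was 1.23 (adjusted p = 1.62e-26, and adjusted p = 0.218 with an estimated correlation).

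Markers of oocytes and early embryos were lower at 3 h and 6 h than in starved larvae. Adult remains in the starved cultures would bring yolk transcripts. Among the 4 vitellogenin genes that were tested, however, the highest starved mean was 0.637 CPM, against a median of 8.22 CPM for the oocyte and embryo markers. Vitellogenin genes outside the tested units were not examined. The choice among the 4 scalings is also argued against, since the highest median of the list at 6 h over them was -1.35. None of the 4 measures total RNA per larva. Unhatched embryos in the starved cultures cannot be told apart from a loss of maternal transcripts in the larvae themselves, because the SD of the fold changes was 2.44 times their median SE, more than a common factor gives, yet mex-3 rose and so has a source in larvae. Maternal transcript loss during recovery stays open as an untested hypothesis.

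Cytosolic ribosomal protein genes were higher at 3 h and 6 h but not at 1 h. The choice among the 4 scalings as the whole cause is argued against by the lowest list median at 6 h over them, 0.614. None of the 4 measures total RNA per larva. A preference for short transcripts is argued against by the 323 genes nearest in exonic length alone, with a median of -0.16 at 6 h (quartiles -0.92 and 0.52, against 0.83 and 1.05 for the list), and by the 56 nearest in length and level together, from which the list median differed by 0.767, although these were still lower in level (median log2 CPM 9.89 against 11.13), as were the 113 nearest in level alone (10.47), whose median was 0.33 (quartiles -0.46 and 0.90), so that a trend with level at the top of the range stays open. Libraries thinned to equal depth left 66 members higher. Genes of this level keep large counts after thinning, so that test could hardly have come out otherwise and decides little about the deeper starved library. A later rise of ribosomal protein transcripts than of ribosome biogenesis transcripts during recovery stays a hypothesis, found and tested on the same data.

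Genes with changed bin use at 6 h were weighed as a set. A shift of coverage along transcripts would place most leading bins at transcript ends, but 32.8% were a first or last bin, against 21% of tested bins, so a shift is argued against as the whole cause and stays open for part of them, with median use of first bins at 0.15 and of last bins at -0.16. Very short bins were not needed, since 65 of 67 genes were also called without bins under 25 bases. Overlap with a bin of the other strand held for 2.99% of the leading bins, and overlap with genes outside the bins was not examined. A change in the transcripts made, such as promoter or splice site choice, may account for prps-1 and was not tested with other data. The gene cdh-10, which gained reads in bins on both sides, has a single annotated transcript. A switch between annotated transcripts therefore cannot account for it. For cyd-1, where bin 8 of the same transcript held reads in starved larvae too, the annotated transcripts do not show which changed. A single annotated transcript was held by 10 of the 45 genes called at 1 h, 5 of 23 at 3 h and 18 of 67 at 6 h. For these genes too, no switch between annotated transcripts is possible.

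Other splits of the 3 starved and 3 libraries at 6 h were also fitted. The real split gave 6044 genes and the highest other 0, and for bin use 38 and 0, so that 1 of the 10 splits reached each real count. For lists the real split gave 21 and the 9 others 10 to 25, the highest other 25, so that 2 of 10 reached it. Camera at the preset correlation called lists in every mixed split, though no gene was called there. Each mixed split holds starved and 6 h libraries on both sides. Feeding then adds to the spread within each side, which lowers gene counts, and part of its difference can remain between the sides. So these splits do not show what is called without any change. The 10 splits are too few for a share under 0.05.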

How the results depend on the processing

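The thinning of libraries to equal depth, the removal of bins under 25 bases and the block on barcode sets were chosen only after the data were seen. No paired analysis was possible because the labels give no replicate numbers or cultures that link samples across groups. This holds for pairing by culture alone. A block on the barcode sets could be fitted, and its results are given below. Barcodes 1 to 4 and 5 to 8 each hold every group once, and what such a set marks is not stated. Deviations from group means correlated at 0.0766 to 0.330 within a set (over 0.1 in 9 of 13 pairs of libraries) and at -0.330 to 0.128 between sets. All 13 pairs within a set were positive, so the sets may act as a batch, which the main fit leaves out. In groups of 2 libraries the deviations mirror each other. Many values between sets therefore repeat those within sets with the sign turned. With barcodes 1 to 4, 5 to 8 and over 8 as a block, 5439 genes were called at 1 h, 5823 at 3 h, 7451 at 6 h, 1801 from 1 h to 3 h and 565 from 3 h to 6 h. Bin use gave 49, 30 and 88 genes. The 65 list calls were kept. No named gene, list or named bin changed direction past its threshold under the alternatives run for it. Named genes were chosen for large changes or small p, so a turn was unlikely for them. The fit to the groups compared alone was not examined for named genes. Camera was not rerun with DESeq2, limma voom or upper-quartile factors. The balance of units higher and lower did turn with scaling, as given in the Results. Of single named genes, 9800 comparisons with an alternative stayed on their side of the threshold and the rest lost the call. For lists 1416 stayed, 83 lost and 31 gained it. For bin use 674 stayed, 56 lost and 4 gained it. Requiring a 1.5-fold change, by construction a stricter test, left 2651 genes at 1 h, 3094 at 3 h, 3920 at 6 h, 374 from 1 h to 3 h and 141 from 3 h to 6 h. From 1 h to 3 h, library totals alone gave 1953 genes, the highest-count bin per gene 584 and a fit to those groups alone 3762. From 3 h to 6 h, DESeq2 gave 682 and the highest-count bin 162. For bin use, the gene-level F test gave 85, 67 and 200 genes at 1 h, 3 h and 6 h, leaving out first and last bins gave 13 at 3 h, and a fit to the groups compared alone gave 38 at 6 h. For these the cause was not tested. With an estimated correlation 0 lists were called. For FPKM, a pseudocount of 5 gave Spearman correlations of 0.938, 0.904 and 0.890 at 1 h, 3 h and 6 h, a pseudocount of 0.1 gave 0.973 at 3 h and 0.976 at 6 h, and a minimum of 1 FPKM gave 0.968 and 0.969. Here too the cause was not tested.

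Leaving out each library in turn gave 63 to 68 list calls, 3307 to 5324 genes at 1 h, 3744 to 5691 at 3 h, 6184 to 6609 at 6 h, 6202 to 7360 at any time, 302 to 1466 from 1 h to 3 h, 120 to 450 from 3 h to 6 h, and for bin use 3 to 127 at 1 h, 5 to 29 at 3 h and 48 to 68 at 6 h. The lowest counts at 1 h, 3 h and any time came without replicate 2 at 1 h, replicate 1 at 3 h and replicate 2 at 1 h. At 2 libraries per group, 2-fold changes were often missed in the simulations (38.8% recovered at 1 h). Those simulations changed far fewer genes than were called in the data, so recovery in the data may differ.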

Other observations

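Genes for handling foreign compounds and bacteria were strongly changed in single members while their lists went both ways. Of 155 cytochrome P450, UDP-glucuronosyltransferase and glutathione S-transferase genes, 56 rose and 34 fell (58 and 36 adjusted over the list alone, adjusted p = 0.0390, and adjusted p = 0.377 with an estimated correlation) at 1 h, 49 rose and 42 fell (53 and 48 adjusted over the list alone, adjusted p = 0.567, and adjusted p = 0.793 with an estimated correlation) at 3 h and 55 rose and 44 fell (56 and 44 adjusted over the list alone, adjusted p = 0.385, and adjusted p = 0.696 with an estimated correlation) at 6 h. The call of the list cytochrome P450, UDP-glucuronosyl and glutathione transferases at 1 h was lost without starved replicate 2 (adjusted p = 0.0863), without replicate 2 at 1 h (adjusted p = 0.0705) and with library totals alone (adjusted p = 0.0737). The P450 gene cyp-37B1 fell from 55.3 ± 4.34 to 0.450 ± 0.0904 CPM at 6 h and ugt-9 rose from 1.38 ± 0.289 to 44.7 ± 0.520 CPM at 1 h. Of 167 lysozyme and antimicrobial effector genes, 45 rose and 27 fell (46 and 27 adjusted over the list alone, adjusted p = 0.173, and adjusted p = 0.604 with an estimated correlation) at 1 h, 46 rose and 44 fell (46 and 46 adjusted over the list alone, adjusted p = 0.760, and adjusted p = 0.907 with an estimated correlation) at 3 h and 56 rose and 45 fell (57 and 47 adjusted over the list alone, adjusted p = 0.316, and adjusted p = 0.696 with an estimated correlation) at 6 h. The C-type lectin gene clec-258 rose from 0.294 ± 0.125 to 20.6 ± 2.42 CPM at 3 h and the saposin-like gene spp-23 from 0.663 ± 0.581 to 57.3 ± 8.45 CPM at 6 h.

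Nuclear hormone receptor and neuropeptide genes fell more often than they rose, and chemoreceptor genes did so at 3 h and 6 h but not at 1 h. Of 205 nuclear hormone receptor genes, 31 rose and 62 fell (33 and 64 adjusted over the list alone, adjusted p = 0.0171, and adjusted p = 0.348 with an estimated correlation) at 1 h, 24 rose and 65 fell (25 and 66 adjusted over the list alone, adjusted p = 0.00187, and adjusted p = 0.269 with an estimated correlation) at 3 h and 27 rose and 75 fell (27 and 74 adjusted over the list alone, adjusted p = 0.00675, and adjusted p = 0.292 with an estimated correlation) at 6 h, and nhr-206 fell from 18.1 ± 4.42 to 2.2 ± 0.183 CPM at 3 h. Of 260 chemoreceptor genes, 41 rose and 27 fell (32 and 19 adjusted over the list alone, adjusted p = 0.171, and adjusted p = 0.696 with an estimated correlation) at 1 h, 14 rose and 36 fell (9 and 28 adjusted over the list alone, adjusted p = 0.494, and adjusted p = 0.828 with an estimated correlation) at 3 h and 12 rose and 65 fell (9 and 61 adjusted over the list alone, adjusted p = 0.00457, and adjusted p = 0.435 with an estimated correlation) at 6 h, where library totals alone lost the call (adjusted p = 0.0784). The diacetyl receptor gene odr-10 fell from 16.6 ± 5.08 to 1.69 ± 0.480 CPM at 1 h. Of 56 neuropeptide genes, 2 rose and 42 fell (2 and 43 adjusted over the list alone, adjusted p = 1.98e-08, and adjusted p = 0.232 with an estimated correlation) at 6 h, after the falls at 1 h.

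Muscle structural genes were called lower at all 3 times at the preset correlation and histone genes at 1 h, while insulin genes were not called. Histone levels here are those of polyadenylated RNA alone, and histone RNA without a poly(A) tail was not measured. Of 34 histone genes, 0 rose and 14 fell (0 and 16 adjusted over the list alone, adjusted p = 1.58e-05, and adjusted p = 0.358 with an estimated correlation) at 1 h, 2 rose and 8 fell (2 and 7 adjusted over the list alone, adjusted p = 0.289, and adjusted p = 0.804 with an estimated correlation) at 3 h and 6 rose and 7 fell (5 and 7 adjusted over the list alone, adjusted p = 0.796, and adjusted p = 0.974 with an estimated correlation) at 6 h, where the median of 0.28 and the mean of -0.06 differed in sign. his-32 rose from 2.09 ± 0.483 to 5.64 ± 0.196 CPM at 6 h. Of 30 muscle structural genes, 5 rose and 13 fell (5 and 13 adjusted over the list alone, adjusted p = 0.0390, and adjusted p = 0.604 with an estimated correlation) at 1 h, 1 rose and 16 fell (3 and 18 adjusted over the list alone, adjusted p = 0.00292, and adjusted p = 0.452 with an estimated correlation) at 3 h and 4 rose and 15 fell (4 and 15 adjusted over the list alone, adjusted p = 0.0307, and adjusted p = 0.597 with an estimated correlation) at 6 h, and the myosin heavy chain gene myo-3 fell from 528 ± 114 to 100.9 ± 17.9 CPM at 3 h. The muscle call was lost without starved replicate 2 at 1 h (adjusted p = 0.148) and at 6 h (adjusted p = 0.0843), without replicate 1 at 1 h (adjusted p = 0.0925) and without replicate 1 at 6 h (adjusted p = 0.108). Of 28 insulin pathway genes, 8 rose and 7 fell (8 and 8 adjusted over the list alone, adjusted p = 0.972, and adjusted p = 0.982 with an estimated correlation) at 1 h, 5 rose and 6 fell (5 and 6 adjusted over the list alone, adjusted p = 0.502, and adjusted p = 0.597 with an estimated correlation) at 3 h and 8 rose and 12 fell (9 and 12 adjusted over the list alone, adjusted p = 0.301, and adjusted p = 0.405 with an estimated correlation) at 6 h. The insulin-like peptide gene daf-28 rose from 6.08 ± 1.83 to 42.8 ± 0.164 CPM and the kinase gene akt-1 fell from 284 ± 32.4 to 29.1 ± 1.42 CPM at 1 h. Of 11 nonsense-mediated decay genes, 2 rose and 1 fell (1 and 0 adjusted over the list alone, adjusted p = 0.972, and adjusted p = 0.982 with an estimated correlation) at 1 h, and the helicase gene smg-2 rose from 37.5 ± 2.29 to 96.8 ± 10.7 CPM. Medians and means differed in sign for some other lists that were not called, namely insulin at 1 h and 3 h, nonsense-mediated decay at 1 h and 6 h, lysozymes at 3 h, oxidative phosphorylation at 3 h and fatty acid oxidation at 6 h.

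Some genes turned from one direction to the other between 1 h and 6 h, all chosen after their values were seen. The cuticle genes rol-8 and cuti-1 had log2 changes of -1.59 and -1.29 at 1 h and of 2.99 and 3.49 at 6 h. The metal transporter gene smf-3 went from 1.72 to -1.01 and the phosphatase gene pho-9 from 0.98 to -3.35.

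The first of 3 hypotheses was that genes close behind another gene of the same strand, as in the operons of C. elegans, rise more at 1 h than other genes of like expression. For 1854 genes within 500 bases downstream of a neighbour the median log2 change was 0.09, against -0.02 for other genes, at percentile 100 of 10000 random lists matched on expression (95% of them between -0.05 and 0.03). The medians at 3 h and 6 h, which the hypothesis did not name, were 0.11 and 0.14. Spacing may go with a rise after feeding, by a small amount, and the functions of such genes were not separated from their spacing. The random lists treat genes as independent, which neighbours need not be, and the percentile measures no spread between libraries.

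The other 2 were negative at the times they named. X-linked genes were tested for lower levels at 6 h than autosomal genes of like expression, and the median of 2042 genes, -0.06, lay at percentile 31.7 of random lists. At 1 h and 3 h, which the hypothesis did not name, the medians were -0.05 and -0.02 against 0.00 and -0.02 for other genes, at percentiles 0.58 and 78.3. The median of X-linked genes at 1 h thus lay below that of matched genes by a small amount. As for spacing, these percentiles treat genes as independent and measure no spread between libraries. Bins found in the minority of transcripts of splicing factor genes were tested for lost use at 1 h, and the median of 23 bins in 4 genes, -0.06, lay at percentile 17.4 of random sets of bins, against 0.06 for other bins.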
